A study of Homo sapiens with 24 samples.

How the data were processed

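Total RNA of 24 HT1376 samples was extracted with Trizol and sequenced as paired reads, per the labels' protocols. The labels name a TruSeq RNA library kit and also describe the libraries as strand specific, and they do not state the strand setting of the counting, so antisense and overlapping genes are uncertain. The submitters' processing notes name STAR 2.7.3a, RSEM 1.3.1 and the genome build hg38, without saying which program wrote the tables. The deposited tables hold whole raw counts per Ensembl gene, 1 table per library with 57500 genes, in the same order in all. No normalisation is recorded, and the values held no fraction or negative number. Gene symbols came from a current table of gene names for 56410 identifiers. GENCODE 29 on GRCh38 held 56898 of the identifiers, 54784 of them with the same start and end as in the tables, and coordinates are those of the tables.

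Counts were analysed in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Genes were kept by filterByExpr over the 8 groups (minimum count 10, minimum total count 15), which left 20472, and libraries were scaled with TMM. All 24 libraries entered 1 model of 8 group means, in which the groups shared the estimates of spread (common biological coefficient of variation 0.0526, median residual degrees of freedom 16). Each comparison was tested with edgeR's robust quasi-likelihood F test, two-sided, with Benjamini-Hochberg adjustment over all tested genes within the comparison and a threshold of 0.05. A gene passed when its adjusted p lay under that threshold, and rose, fell or changed is written only of such genes. Values after ± are standard errors for log2 fold changes, computed as the absolute log2 fold change over the square root of F, and standard deviations over 3 libraries for CPM. Group values are mean CPM per TMM-scaled library. Log CPM for principal components and correlations of libraries used a prior count of 2. To compare numbers of detected genes, counts were thinned to the smallest library's total.

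There were 11 comparisons. CPI-0209 was set against DMSO within each of the 4 combinations of line and dox. Dox was set against no dox in each line with DMSO, and the ARID1A line against the control line without dox and with DMSO. Interaction contrasts gave the differences of the dox response between lines, of the CPI-0209 response with and without dox in each line, and of the CPI-0209 response between lines. Replicate letters were not treated as pairs.

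Before the data were examined, 29 gene lists with 659 genes were written from general knowledge, of which 657 are in the files, together with the design, the alternatives and the rule for named genes. Within each list, genes past the threshold were counted over all tested genes, and again adjusted over the list alone, which is given where the counts differ. Lists were tested against the other genes with limma's camera at a preset correlation of 0.01 and again with an estimated correlation, with Benjamini-Hochberg adjustment over the 29 lists of a comparison, and with fry. A list is called where camera's adjusted p lay under 0.05 at the preset correlation, and the call held with an estimated correlation unless the value with it stands beside it. Of 319 list and comparison pairs, 117 were called at the preset correlation, 44 with an estimated one and 190 by fry, which does not compare a list with other genes. Overlaps used one-sided Fisher's exact tests over the tested genes.

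The genes named were chosen by a rule. *ARID1A* and *EZH2* were always named. For each comparison the rule took genes with an official symbol that passed, had at least 1 CPM in the higher group and, outside interactions, had all 3 libraries of one group above the other 3. It kept the 10 with the largest change each way in the main comparisons and 5 in the others. It added up to 4 members of each list with the smallest adjusted p, all passing PRC2 and SWI/SNF members, and the 10 genes each way with the largest shared change. The text leaves some out for length, and a few others are not reported here. Paralogs and multigene families (HLA, keratin 6, *MAGE*, *CTRB1*) and protocadherin genes that overlap each other are uncertain.

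Where a group had no count for a gene, the change is given as a bound against 3 counts over the group. With 1 to 3 counts it is a ratio with a 95% exact binomial counting interval. No fitted fold change is given for such genes.

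The procedure was tested on simulated counts drawn from the real means and library sizes, with 200 genes changed, 50 for each fold. The changed genes were drawn from those with a mean of at least 1 CPM, so recovery of lower genes was not measured. For CPI-0209 in the control line without dox (20223 genes), 86% of genes changed 1.5-fold were recovered, 90.0% at 2-fold and 98% at 4-fold, and 4.82% of calls were false. For dox in the ARID1A line (20278 genes) the shares were 86%, 92% and 98%, with 8.02% false. For the difference of the CPI-0209 response with dox in the ARID1A line (20139 genes) they were 54%, 88% and 96%, with 3.08% false. For that difference in the control line (20271 genes) they were 68%, 76% and 96%, with 5.04% false. At the smallest simulated change, 0.32 on the log2 scale, 42%, 68%, 14% and 24% were recovered in these 4 comparisons, so many small changes were missed in the simulation. In the data 10089, 12416 and 6533 genes passed for CPI-0209 in the control line, dox in the ARID1A line and the ARID1A line's difference. The adjusted threshold is less strict where more genes change than the 200 simulated. The shares therefore do not measure recovery there. Increases and decreases were equally many, so a lopsided response was not simulated. With no list changed, camera called 1, 0, 0 and 1 of the 29 lists in these simulations. Genes were drawn independently of each other, so these numbers do not show how often camera errs where genes are correlated.

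The alternatives were RLE and upper quartile scaling, no filter beyond 1 count in any library, a filter of at least 1 CPM in at least 3 libraries, DESeq2, a block for the replicate letter, only the groups compared, a minimum log2 fold change of 1, and each library left out in turn. DESeq2 was run on all genes with at least 1 count in any library. The lists without the ARID1A line with dox and DMSO replicate A were added after that library was seen to stand apart. Lanes held 9 samples each per the labels, without an assignment, so lanes were not tested. No library was left out. Splicing, sequence variants and the split of endogenous from construct *ARID1A* were not analysed here, because the tables hold 1 count per gene.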

Results

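RNA of HT1376 cells, a urothelial bladder cancer line with a mutated *ARID1A* gene, was sequenced in 24 libraries. *ARID1A* encodes a subunit of the SWI/SNF chromatin remodelling complex, and *EZH2* encodes the histone methyltransferase of the polycomb repressive complex PRC2. A control line carried the doxycycline-inducible system, and a clonal line carried it with inducible *ARID1A*. Cells received no doxycycline or 50 ng/ml doxycycline (dox) for 24 hours, and then DMSO or 250 nM of the EZH2 inhibitor CPI-0209 for 4 days. These settings made 8 groups of 3 libraries. Total counts per library ran from 22284090 to 29165639. After the filter, 20472 genes were tested, 15141 of them protein-coding. The labels do not state that the 3 libraries of a group were separate cultures, so the p-values measure only the spread between these samples, which may be technical.

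The libraries grouped by treatment on principal components of all tested genes. The first component held 45.1% of the variance and placed the DMSO libraries between -90.3 and -49.7 and the CPI-0209 libraries between 55.7 and 78.3. The next held 30.6% and set the 6 libraries of the ARID1A line with dox, at 97.7 or more, apart from all others, at -15.1 or less. Mitochondrially encoded transcripts took 2.51% ± 0.210 of counts in the ARID1A line with dox and DMSO (mean and SD, n = 3) and 2.84% ± 0.0471 with dox and CPI-0209. In the other 6 groups their mean share lay between 4.04% and 4.72%. 1 library, ARID1A line with dox and DMSO replicate A, stood apart from its group, with a root mean square deviation of 0.287 log2 units against 0.177 to 0.252 in the other 23. Its 7SL RNA counts reached 708 CPM against 27.1 to 202 CPM elsewhere, its *MALAT1* 2414 CPM against 922 to 1905 CPM, and its replication-dependent histone mRNAs 314 CPM against 192 to 287 CPM.

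*ARID1A* (ENSG00000117713, chromosome 1, 26693236 to 26782104 on GRCh38, plus strand) was present in both lines and was induced only where dox met the construct. Without dox and with DMSO it stood at 132 ± 1.28 CPM in the control line and 172 ± 5.99 CPM in the ARID1A line (mean and SD, n = 3). Dox raised it to 3578 ± 74.0 CPM in the ARID1A line, which was 20.8-fold (log2 fold change 4.38 ± 0.05, SE, edgeR adjusted p = 1.10e-37), and 25.5-fold under CPI-0209, to 3821 ± 123 CPM. In the control line dox left it at 120.3 ± 5.31 CPM (edgeR adjusted p = 0.226), and the difference between the lines' dox responses was 4.51 ± 0.07. These counts do not separate the endogenous transcripts from those of the construct. The uninduced ARID1A line held slightly more than the control line (log2 difference 0.39 ± 0.05, edgeR adjusted p = 3.00e-08). CPI-0209 lowered *ARID1A* by little in the uninduced ARID1A line (log2 fold change -0.20 ± 0.05, edgeR adjusted p = 5.58e-04). It did not pass in the control line without dox or in the induced line.

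*EZH2* (ENSG00000106462, chromosome 7, 148807383 to 148884321, minus strand) kept similar transcript levels throughout, from 56.0 to 73.9 CPM as group means. CPI-0209 acts on the enzyme, and in the control line the transcript rose slightly with it, from 64.7 ± 1.57 to 73.9 ± 3.20 CPM (log2 fold change 0.19 ± 0.05, edgeR adjusted p = 0.00292). It did not pass in the ARID1A line without dox (log2 fold change 0.02 ± 0.05, edgeR adjusted p = 0.820). *EZH2* rose with dox in the ARID1A line by 0.25 ± 0.05 and was lower in the uninduced ARID1A line than in the control line (log2 difference -0.21 ± 0.05).

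**Figure D1:**
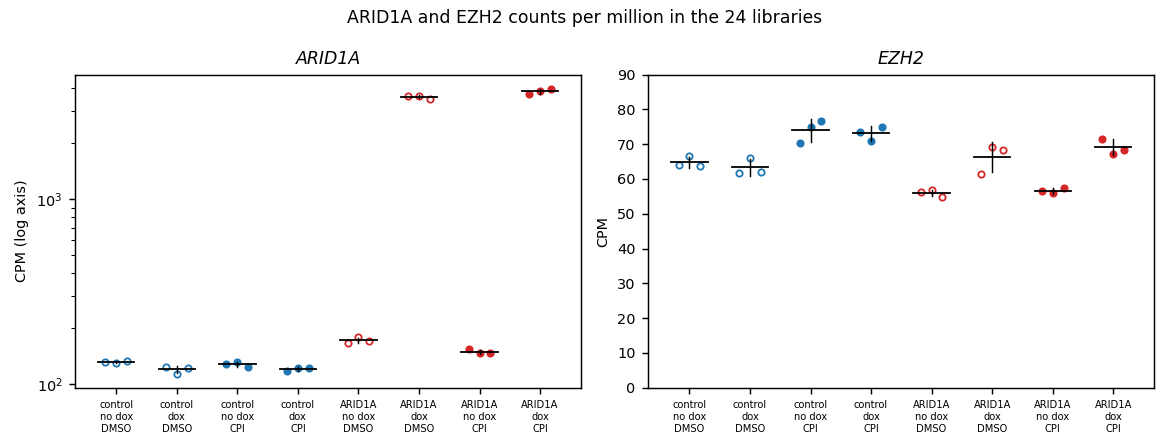
*ARID1A* (log axis) and *EZH2* (linear axis from 0) in CPM in every library of the 8 groups, blue for the control line and red for the ARID1A line, open for DMSO and filled for CPI-0209, with the mean as a bar and ±SD as a line (n = 3). *ARID1A* stood at 3578 and 3821 CPM in the 2 induced groups and at 172 CPM or less in the other 6, while *EZH2* means lay between 56.0 and 73.9 CPM.

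The comparison of CPI-0209 with DMSO in the control line without dox asked which genes respond to EZH2 inhibition in *ARID1A*-mutant cells. CPI-0209 raised the whole tested MHC class II antigen presentation pathway, squamous differentiation genes, neuronal genes and developmental regulators that polycomb complexes keep silent in many tissues. *HLA-DRA* (ENSG00000204287, chromosome 6, 32439842 to 32445046) rose from 0.386 ± 0.108 to 11.5 ± 1.80 CPM (log2 fold change 4.88 ± 0.20, SE, edgeR adjusted p = 1.48e-21). *CIITA*, the regulator of this pathway, rose from 1.99 ± 0.130 to 17.8 ± 1.04 CPM, and *CD74*, its invariant chain, from 4.75 to 68.4 CPM. All 11 tested class II genes rose at least 2-fold, with *HLA-DQB1* (4.18 ± 0.12) and *HLA-DRB1* (4.81 ± 0.19) uncertain between paralogs (camera adjusted p = 9.26e-23). *SBSN* (ENSG00000189001, chromosome 19, 35523367 to 35528351), an epidermal differentiation gene, rose from 1.74 ± 0.207 to 131 ± 11.4 CPM. All 31 tested squamous differentiation genes rose, 25 of them at least 2-fold, among them *SPRR1A* (3.49 ± 0.10) and *KLK7* (1.54 ± 0.05) (camera adjusted p = 3.01e-29).

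37 of 44 developmental transcription factors rose and 1 fell (37 higher and 2 lower adjusted over the list alone), 32 at least 2-fold higher (camera adjusted p = 6.87e-08). They included *SIM2* (2.85 ± 0.17), *GATA6* (1.52 ± 0.10) and *HOXB7* (5.35 ± 0.32). 16 of 19 axon and neuronal genes rose and 1 fell (camera adjusted p = 1.10e-12), led by *DPYSL3* (4.75 ± 0.14), *STMN3* (2.99 ± 0.09) and *CHGA* (2.50 ± 0.11). 14 of 19 basal urothelial markers rose and 5 fell (camera adjusted p = 2.61e-07). The basal keratin *KRT5* went from 36.7 ± 1.87 to 263 ± 20.6 CPM, *KRT16* rose by 2.24 ± 0.08 and *CD44* by 1.42 ± 0.04. These calls held with an estimated correlation, as did the other camera calls printed without a value for it.

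Other groups passed camera at its preset correlation alone. 21 of 28 chemokines and NF-kB targets rose and 4 fell (camera adjusted p = 2.84e-08, adjusted p = 0.0602 with an estimated correlation). They included the T-cell chemokine *CXCL10* (2.43 ± 0.09), *LIF* (1.83 ± 0.06) and *IL32* (1.71 ± 0.07). 13 of 20 genes described as EZH2-repressed in tumours rose and 4 fell (14 higher and 4 lower adjusted over the list alone; camera adjusted p = 7.91e-04, adjusted p = 0.0788 with an estimated correlation). *DKK1* (3.06 ± 0.09) and *PRDM1* (2.96 ± 0.10) were higher and *TIMP3* (-1.11 ± 0.05) lower. 13 of 22 epithelial identity genes rose and 5 fell (14 higher and 5 lower adjusted over the list alone; camera adjusted p = 0.0141, adjusted p = 0.196 with an estimated correlation), with *KRT23* (3.58 ± 0.09) and *OVOL1* (1.52 ± 0.08) rising. 13 of 21 mesenchymal genes rose and 4 fell (camera adjusted p = 0.0298, adjusted p = 0.312 with an estimated correlation). Of these *COL1A1* (1.92 ± 0.06) and *THY1* (3.52 ± 0.16) were higher and *COL3A1* (-1.70 ± 0.06) lower. Markers of other cell types also rose. 7 of 9 endothelial markers rose and 1 fell (camera adjusted p = 0.0298, adjusted p = 0.0697 with an estimated correlation), with *ESAM* at 2.60 ± 0.18. 5 of 8 fibroblast markers rose and 1 fell (camera adjusted p = 0.0459, adjusted p = 0.0895 with an estimated correlation), with *LUM* at 3.05 ± 0.30. 3 of 6 leukocyte markers rose and 1 fell, without a camera call.

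The remaining lists passed camera under neither correlation. 11 of 22 luminal urothelial markers rose and 6 fell, with *GRHL3* (2.12 ± 0.07) and *FABP4* (5.73 ± 0.31) rising. 13 of 38 interferon-stimulated genes rose and 10 fell (13 higher and 11 lower adjusted over the list alone), with *ISG20* (1.06 ± 0.10) rising and *SAMD9L* (-0.67 ± 0.08) falling. 6 of 20 MHC class I genes rose and 8 fell (6 higher and 9 lower adjusted over the list alone), with *HLA-F* at 1.12 ± 0.07 and *ERAP1* at -0.66 ± 0.05. 3 of 7 CDK inhibitors rose and 2 fell, with *CDKN1C* going from 0.463 to 8.70 CPM and *CDKN2A* falling (-0.71 ± 0.06). 5 of 30 S phase genes rose and 8 fell (5 higher and 7 lower adjusted over the list alone). 2 of 30 G2/M genes rose and 4 fell (1 higher and 3 lower adjusted over the list alone), and 5 of 19 replication-dependent histone mRNAs rose and 1 fell. 9 of 22 p53 targets rose and 6 fell, and 12 of 25 immediate-early and MAPK feedback genes rose and 10 fell (13 higher and 10 lower adjusted over the list alone). 7 of 25 integrated stress response genes rose and 7 fell (9 higher and 7 lower adjusted over the list alone), and 3 of 15 unfolded protein response genes rose and 3 fell. 6 of 21 hypoxia and glycolysis genes rose and 10 fell, and 5 of 24 cholesterol biosynthesis genes rose and 3 fell. 7 of 21 germline genes rose and 6 fell (7 higher and 7 lower adjusted over the list alone), and none of the 13 mitochondrially encoded mRNAs passed. 4 of 13 genes of the PRC2 list rose and 5 fell, with *EZHIP* (2.18 ± 0.14), listed there though not a subunit, higher and *AEBP2* (-0.80 ± 0.10) lower. 6 of 27 SWI/SNF subunits rose and 8 fell, a majority that turned to 7 or 8 higher and 6 lower under the other scalings, with *SMARCD3* (1.86 ± 0.12) higher and *SMARCC1* (-0.38 ± 0.05) lower.

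The largest increases started from very few counts. *RPS6KA2* (ENSG00000071242, chromosome 6, 166409364 to 166906451), a ribosomal S6 kinase gene, rose from 0.0403 to 16.2 ± 0.325 CPM, a ratio of 409 with a 95% exact binomial counting interval of 139.6 to 1985. The cytochrome gene *CYP4F22* had no count with DMSO and was at least 43.5-fold higher, taking 3 counts over the group as the floor. The collagenase gene *MMP1* (ENSG00000196611, chromosome 11, 102789920 to 102798160) rose from 0.119 ± 0.00544 to 17.6 ± 1.45 CPM (7.15 ± 0.23, edgeR adjusted p = 8.91e-25). Decreases were smaller, led by the lectin receptor *CLEC1A*, from 4.77 ± 0.187 to 0.471 ± 0.157 CPM (-3.33 ± 0.20, edgeR adjusted p = 1.40e-16). *ATOH8* (-2.47 ± 0.20), *FAM174B* (-2.05 ± 0.07), *DUSP2* (-2.00 ± 0.12) and *ID1*, from 547 ± 41.5 to 139 ± 9.23 CPM, also fell. For genes such as these, ranked by size of change, all 3 libraries of one group lay above all 3 of the other. Intervals and floors cover counting error only, because PCR reads without molecular identifiers are not independent molecules.

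In all, 10089 of the 20472 genes passed edgeR's adjusted p threshold of 0.05, 5421 higher and 4668 lower, and 3085 higher and 271 lower changed at least 2-fold. The genes at least 2-fold higher had a median of 0.226 CPM with DMSO and 1.43 CPM with CPI-0209, and 74.7% of them stood under 1 CPM with DMSO, against 29.4% of all tested genes. At equal depth, the number of genes with a count rose from 27684 ± 166 to 30208 ± 311 (mean and SD, n = 3).

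**Figure D2:**
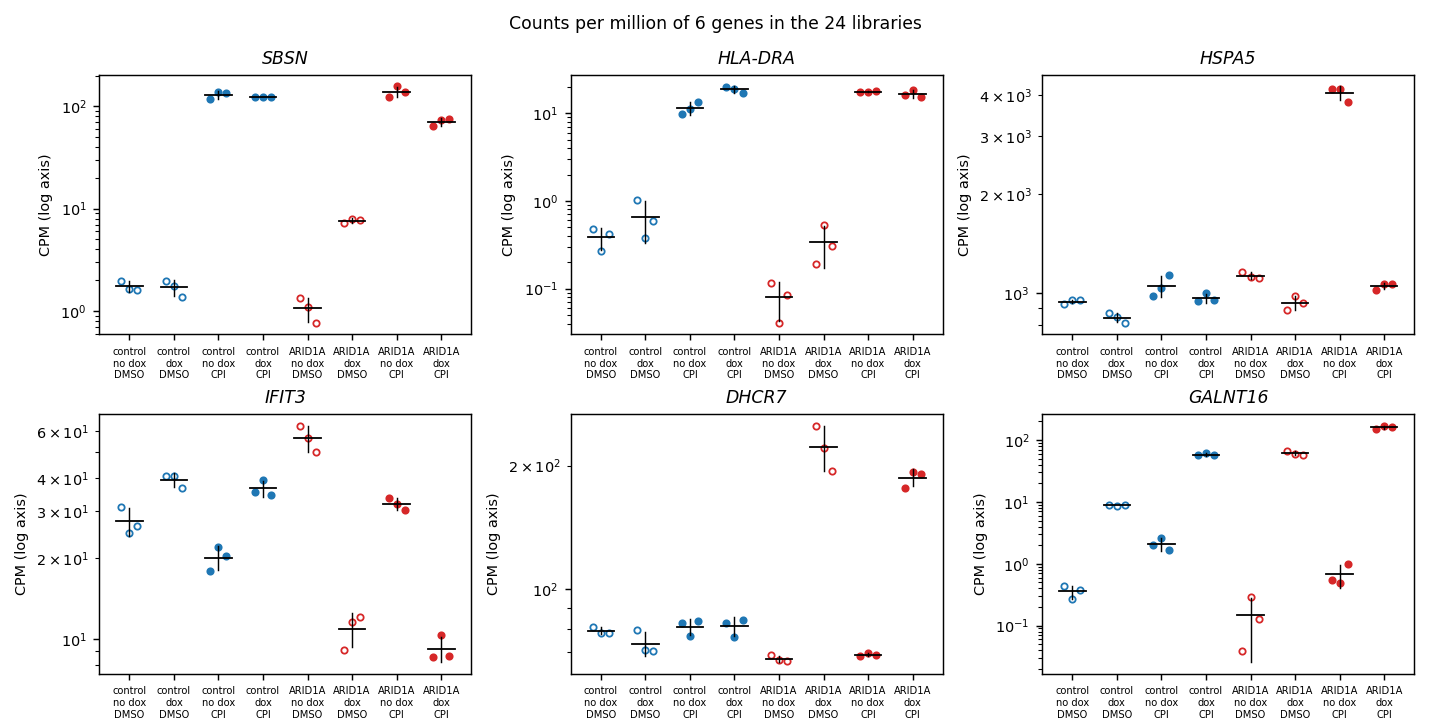
CPM of *SBSN*, *HLA-DRA*, *HSPA5*, *IFIT3*, *DHCR7* and *GALNT16* in every library of the 8 groups, with blue for the control line, red for the ARID1A line, open for DMSO and filled for CPI-0209, the mean as a bar and ±SD as a line (n = 3). *HSPA5* stood highest in the ARID1A line with CPI-0209 and no dox, at 4047 CPM, and *GALNT16* rose with dox in both lines.

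In the control line with dox, CPI-0209 raised the same families. All 11 class II genes rose (camera adjusted p = 2.22e-28), with *HLA-DRB1* at 5.22 ± 0.17, as did all 31 squamous genes (camera adjusted p = 5.29e-26). 38 of 44 developmental transcription factors rose and 2 fell (39 higher and 3 lower adjusted over the list alone; camera adjusted p = 8.33e-09), with *PAX9* at 3.71 ± 0.19. 16 of 19 neuronal genes rose (17 higher and 0 lower adjusted over the list alone; camera adjusted p = 7.99e-12). 23 of 28 chemokines and NF-kB targets rose and 4 fell (camera adjusted p = 4.54e-10), and 13 of 20 EZH2-repressed genes rose and 3 fell (camera adjusted p = 4.50e-05). 14 of 19 basal markers rose and 5 fell (camera adjusted p = 5.38e-09), with *KRT5* at 3.19 ± 0.08. 22 of 38 interferon-stimulated genes rose and 6 fell, without a camera call (camera adjusted p = 0.276), with *MX2* (1.75 ± 0.13) higher. The cardiac regulator *GATA4* had no count with DMSO and was at least 73.2-fold higher, while *CLEC1A* (-3.86 ± 0.22) and *SLC2A5* (-2.67 ± 0.25) fell. With edgeR, 10363 genes passed, 5568 higher and 4795 lower, with 3171 higher and 251 lower at least 2-fold.

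In the ARID1A line without dox, CPI-0209 raised class II and differentiation genes and, to an extent that differed from the control line, endoplasmic reticulum stress genes. *HSPA5* (ENSG00000044574, chromosome 9, 125234853 to 125241330), the main chaperone of that compartment, rose from 1131 ± 24.4 to 4047 ± 199.7 CPM (edgeR adjusted p = 2.19e-26). Its log2 fold change was 1.84 ± 0.05, against 0.16 ± 0.05 in the control line. All 15 unfolded protein response genes rose, 11 at least 2-fold (camera adjusted p = 1.36e-28), among them *SDF2L1* (2.19 ± 0.07), *HYOU1* (1.68 ± 0.05) and *PDIA4* (1.37 ± 0.05). 21 of 25 ATF4-type integrated stress response genes rose and 3 fell (22 higher and 3 lower adjusted over the list alone; camera adjusted p = 4.60e-12), with *STC2* (2.32 ± 0.07), *ALDH1L2* (2.54 ± 0.11) and *ASNS* (1.34 ± 0.06) higher.

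All 11 class II genes rose in that group too (camera adjusted p = 8.63e-39), *HLA-DRA* from 0.0812 ± 0.0383 to 17.6 ± 0.228 CPM. 28 of 31 squamous genes rose (29 higher and 0 lower adjusted over the list alone; camera adjusted p = 2.33e-21), with *SBSN* at 7.01 ± 0.12 and *S100A7* at 4.06 ± 0.12. 36 of 44 developmental factors rose and 2 fell (camera adjusted p = 1.16e-06), and 14 of 19 neuronal genes rose (16 higher and 0 lower adjusted over the list alone; camera adjusted p = 2.76e-09). 22 of 28 chemokines and NF-kB targets rose and 2 fell (camera adjusted p = 2.76e-09), with *CXCL1* at 3.95 ± 0.17. 14 of 20 EZH2-repressed genes rose and 4 fell (camera adjusted p = 2.04e-06). Interferon-stimulated genes mostly fell, with *SAMD9L* at -0.92 ± 0.07 and *IFIT3* at -0.82 ± 0.09. 2 of 38 of them rose and 29 fell (camera adjusted p = 1.19e-04, adjusted p = 0.457 with an estimated correlation). S phase genes mostly fell by small amounts, such as *MCM4* (-0.42 ± 0.04) and *PCNA* (-0.41 ± 0.05). 2 of 30 of them rose and 21 fell (2 higher and 23 lower adjusted over the list alone; camera adjusted p = 0.00422, adjusted p = 0.215 with an estimated correlation). The kidney and mesothelial regulator *WT1* had no count with DMSO and was at least 184-fold higher, and the metalloprotease gene *ADAMTS8* at least 235-fold. *EDNRB* (-2.29 ± 0.22) and *NAV3* (-2.04 ± 0.13) fell. With edgeR, 10783 genes passed, 5365 higher and 5418 lower, and 3119 higher and 252 lower at least 2-fold. Higher calls were 49.8% of these and 56.3% to 59.3% under the other scalings, so the side with more genes was not fixed.

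In the ARID1A line with dox, CPI-0209 still raised class II and developmental genes, while squamous genes had no camera call. *HLA-DRA* rose by 5.53 ± 0.20, with all 11 class II genes higher (camera adjusted p = 1.30e-31). 38 of 44 developmental factors rose and 1 fell (40 higher and 1 lower adjusted over the list alone; camera adjusted p = 8.40e-13), with *GATA4* (6.82 ± 0.27) and *MSX1* (4.53 ± 0.20). The homeobox gene *HOXB3* had no count with DMSO and was at least 61.1-fold higher. 10 of 19 neuronal genes rose and 1 fell (camera adjusted p = 1.71e-05), led by *NEFM* (5.55 ± 0.28). 11 of 20 EZH2-repressed genes rose and 5 fell (11 higher and 6 lower adjusted over the list alone; camera adjusted p = 0.00307, adjusted p = 0.263 with an estimated correlation). 11 of 31 squamous genes rose and 4 fell (13 higher and 4 lower adjusted over the list alone; camera adjusted p = 0.388), and 6 of 15 unfolded protein response genes rose and 2 fell. 2 of 22 epithelial identity genes rose and 16 fell (camera adjusted p = 0.0190, adjusted p = 0.324 with an estimated correlation), with *CLDN3* at -0.84 ± 0.09. 3 of 13 mitochondrially encoded mRNAs rose and 1 fell (2 higher and 0 lower adjusted over the list alone), against 0 higher and 1 lower without the replicate A that stood apart. *RARRES1* (-1.58 ± 0.13) and *KCNMB4* (-1.49 ± 0.09) were among the largest decreases. With edgeR, 9918 genes passed, 5267 higher and 4651 lower, and 2716 higher and 154 lower at least 2-fold. Only 6999 passed when the libraries of these groups alone were fitted. The model of all libraries shares its spread with groups whose replicates lay closer together. In this DMSO group replicate A correlated with B and C at 0.992 and 0.990 (Pearson, log CPM). All other replicate pairs reached 0.993 or more. The p-values that involve this group may therefore be too small.

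Across the 4 settings, which share no library, 1828 genes rose at least 2-fold in all of them, where 9.66 would be expected from independent sets, and 12 fell at least 2-fold in all. Across the 20472 genes the log2 fold changes of the control line without dox correlated with those of the control line with dox (Pearson 0.926, Spearman 0.842), the ARID1A line without dox (0.876 and 0.748) and the ARID1A line with dox (0.747 and 0.539). Genes are not independent replicates, so these describe the libraries.

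**Figure D3:**
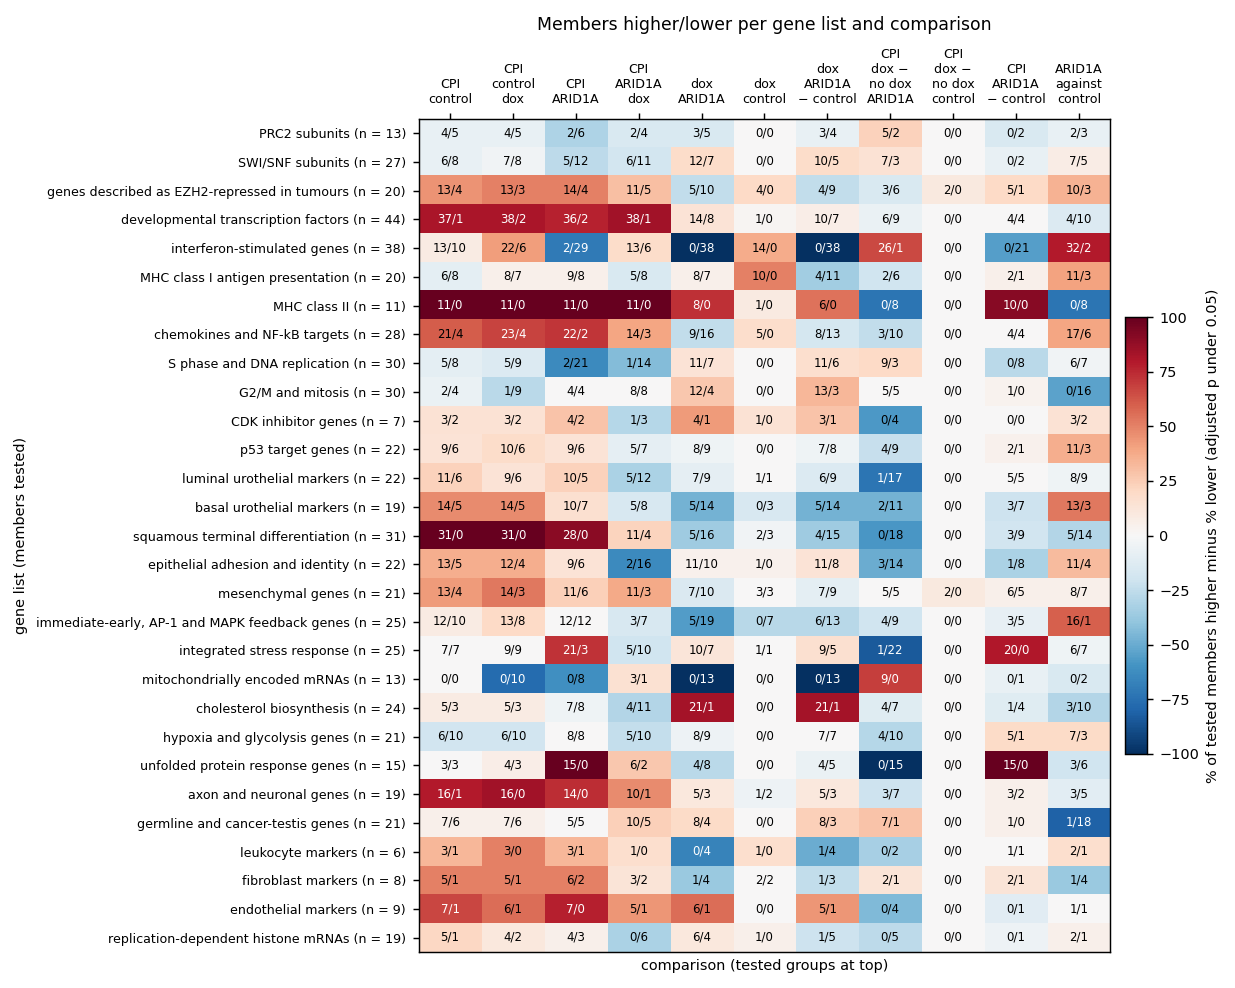
Number of genes higher and lower past the threshold in each of the 29 gene lists (lines of the map) and 11 comparisons (columns), with colour for the percent of tested members higher minus the percent lower. MHC class II was higher in all 4 CPI-0209 comparisons, and interferon-stimulated genes were lower for all 38 members with dox in the ARID1A line.

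The comparison of dox with no dox in the ARID1A line with DMSO asked which genes respond when *ARID1A* is induced. Its RNA stood at 3578 CPM with dox against 172 CPM without, and its protein was not measured here. Only 1 clone was studied, so responses of this clone cannot be told apart from those of induced *ARID1A* in general. Most basal markers and all tested interferon-stimulated genes fell, and single genes rose from very low levels. Filamin C, *FLNC* (ENSG00000128591, chromosome 7, 128830377 to 128859274), rose from 1.64 ± 0.678 to 627 ± 59.7 CPM (8.58 ± 0.12, SE, edgeR adjusted p = 3.07e-34). The mucin *MUC4* rose from 0.944 to 164 CPM and the adhesion molecule *MCAM* from 2.77 to 466 ± 18.5 CPM. The glycosyltransferase gene *GALNT16* (ENSG00000100626, chromosome 14, 69259277 to 69357033) rose from 0.151 ± 0.125 to 61.4 ± 4.72 CPM (8.63 ± 0.17), but it also rose with dox in the control line. The basal lineage factor *TP63* (ENSG00000073282, chromosome 3, 189631416 to 189897279) fell from 110.1 ± 2.83 to 5.86 ± 0.905 CPM (-4.22 ± 0.08, edgeR adjusted p = 1.89e-32).

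With *TP63*, the basal adhesion genes *DSC3* (-1.84 ± 0.07) and *ITGB4* (-1.58 ± 0.06) fell. 5 of 19 basal markers rose and 14 fell (camera adjusted p = 2.62e-07). The desmosomal cadherin *DSG1* fell from 200.1 ± 13.1 to 3.60 ± 0.344 CPM, with *SPRR3* at -2.07 ± 0.07 and *KRT10* at -2.05 ± 0.07. 5 of 31 squamous genes rose and 16 fell (6 higher and 17 lower adjusted over the list alone; camera adjusted p = 2.02e-04, adjusted p = 0.295 with an estimated correlation). Interferon-stimulated genes were lower for all 38 tested, 26 at least 2-fold (camera adjusted p = 3.35e-20, adjusted p = 0.140 with an estimated correlation). Among them *IFIT3* went from 56.4 ± 6.40 to 10.9 ± 1.62 CPM, and *OASL* (-2.59 ± 0.11) and *SAMD9L* (-1.72 ± 0.08) fell. 5 of 25 immediate-early and MAPK feedback genes rose and 19 fell (camera adjusted p = 2.66e-05, adjusted p = 0.412 with an estimated correlation), with *DUSP6* (-3.45 ± 0.09), *SPRY2* (-1.69 ± 0.06) and *EGR1* (-1.42 ± 0.06) lower. All 13 mitochondrially encoded mRNAs fell (camera adjusted p = 3.12e-06, adjusted p = 0.295 with an estimated correlation), such as *MT-CO1* (-0.92 ± 0.05), as did the mitochondrial share of counts. 7 of 21 mesenchymal genes rose and 10 fell (camera adjusted p = 2.71e-04, adjusted p = 0.143 with an estimated correlation), with *SPARC* going from 22.3 to 0.293 CPM and *COL3A1* (-4.30 ± 0.07) and *SNAI2* (-3.28 ± 0.10) lower. Their median log2 fold change was 0.07 and their mean -0.67, and camera's direction was down. 1 of 8 fibroblast markers rose and 4 fell (camera adjusted p = 0.00110), *COL1A2* (-4.35 ± 0.21) against *COL1A1* (1.31 ± 0.07).

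Cholesterol biosynthesis rose. *DHCR7* went from 67.4 ± 1.16 to 222 ± 28.2 CPM, and *FDFT1* (1.17 ± 0.05) rose with it. 21 of 24 genes of the pathway rose and 1 fell, 12 at least 2-fold higher (camera adjusted p = 1.15e-14). 4 of 7 CDK inhibitors rose and 1 fell (camera adjusted p = 0.0232, adjusted p = 0.412 with an estimated correlation), with *CDKN2D* (2.13 ± 0.10) and *CDKN2C* (1.10 ± 0.07) higher. 8 of 11 MHC class II genes rose, all 8 at least 2-fold, without a camera call (camera adjusted p = 0.106). *CIITA* rose by 1.47 ± 0.15 and *CD74* by 1.94 ± 0.17. For *HLA-DRA* the level stayed near the floor, from 0.0409 to 0.117 CPM per library without dox and 0.189 to 0.530 CPM with it. The control line without dox and with DMSO held 0.265 to 0.476 CPM. CPI-0209 without dox took the ARID1A line to 17.4 to 17.8 CPM.

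Other groups held genes in both directions and passed camera under neither correlation. 12 of 27 SWI/SNF subunits rose and 7 fell (12 higher and 8 lower adjusted over the list alone), the induced *ARID1A* among those higher, with *SMARCA2* (0.47 ± 0.05) higher and *BCL7A* (-0.90 ± 0.06) and *SMARCC1* (-0.65 ± 0.05) lower. 3 of 13 genes of the PRC2 list rose and 5 fell, with *EZH1* (-0.88 ± 0.06) and *AEBP2* (-0.97 ± 0.10) lower. 5 of 20 EZH2-repressed genes rose and 10 fell, with *NGFR* (-3.25 ± 0.08) and *FBXO32* (-2.30 ± 0.06) lower. 14 of 44 developmental factors rose and 8 fell (13 higher and 8 lower adjusted over the list alone), with *GATA6* (2.07 ± 0.09) higher. 9 of 28 chemokines and NF-kB targets rose and 16 fell, with *IL32* (2.52 ± 0.07) higher and *CXCL10* (-4.44 ± 0.17) lower. 8 of 20 MHC class I genes rose and 7 fell, with *TAP2* (1.51 ± 0.06) higher and *ERAP2* (-1.46 ± 0.09) lower. 11 of 22 epithelial genes rose and 10 fell, with *EPCAM* (1.51 ± 0.06) and *CDH1* (1.08 ± 0.05) higher and *KRT23* (-4.89 ± 0.10) lower. 10 of 25 integrated stress response genes rose and 7 fell (11 higher and 7 lower adjusted over the list alone), with *VLDLR* (4.71 ± 0.13) higher, and 4 of 15 unfolded protein response genes rose and 8 fell (5 higher and 8 lower adjusted over the list alone). 8 of 21 hypoxia genes rose and 9 fell, with *P4HA2* (2.65 ± 0.06) higher and *HK2* (-1.79 ± 0.06) lower. 11 of 30 S phase genes rose and 7 fell. 12 of 30 G2/M genes rose and 4 fell, with *FOXM1* (0.77 ± 0.06) and *PLK1* (0.73 ± 0.06) higher. Without replicate A of the induced group, 19 G2/M genes were higher and 4 lower. 6 of 19 histone mRNAs rose and 4 fell, and 2 were higher and 4 lower without that library.

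Among the largest changes with a count in both groups were *IGFL1* (8.10 ± 0.20) and *NPPB* (7.91 ± 0.26) upwards, and *TNFSF18*, from 66.7 to 0.629 CPM, *CLCA2* (-6.62 ± 0.28), *DHRS9* (-6.79 ± 0.32) and *SPP1* (-6.44 ± 0.21) downwards. *SARDH* had no count without dox and was at least 32.0-fold higher, and *VIT* had none with dox and was at least 55.3-fold lower. With edgeR, 12416 genes passed, 6205 higher and 6211 lower, with 1652 higher and 2389 lower at least 2-fold. The share of higher calls ran from 48.8% to 52.3% under the other scalings. The lower set had a median of 2.80 CPM without dox and 0.765 CPM with it.

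Dox in the control line asked what doxycycline does without induced *ARID1A*. Its effects were few and small apart from a handful of genes. *GALNT16* rose from 0.359 ± 0.0866 to 8.89 ± 0.134 CPM, 24.9-fold (4.62 ± 0.20, edgeR adjusted p = 2.15e-18). *TMC3* rose from 0.464 to 2.42 CPM (2.38 ± 0.24) and *IGFN1* by 1.96 ± 0.25. Interferon-stimulated genes went up, the opposite of the ARID1A line, with *IFIT3* at 0.52 ± 0.09 and *EPSTI1* at 0.60 ± 0.11. 14 of 38 of them rose (34 higher and 0 lower adjusted over the list alone; camera adjusted p = 1.79e-35), and 4 to 24 did with 1 library left out. 10 of 20 MHC class I genes rose (16 higher and 1 lower adjusted over the list alone; camera adjusted p = 2.17e-23), with *HLA-B* at 0.47 ± 0.07, and 6 to 8 did with 1 library left out. 7 of 25 immediate-early and MAPK feedback genes fell (1 higher and 9 lower adjusted over the list alone; camera adjusted p = 2.27e-10, adjusted p = 0.264 with an estimated correlation), with *DUSP4* at -0.58 ± 0.05 and *DUSP6* at -0.50 ± 0.07, and 3 to 5 did with 1 library left out. 3 of 19 basal markers fell (0 higher and 4 lower adjusted over the list alone; camera adjusted p = 6.37e-06, adjusted p = 0.0606 with an estimated correlation), with *KRT5* at -0.74 ± 0.08. 5 of 28 chemokines and NF-kB targets rose (8 higher and 1 lower adjusted over the list alone; camera adjusted p = 9.54e-04, adjusted p = 0.345 with an estimated correlation), with *TNF* at 0.85 ± 0.13. 2 of 31 squamous genes rose and 3 fell (3 higher and 6 lower adjusted over the list alone; camera adjusted p = 0.0373, adjusted p = 0.465 with an estimated correlation). None of the 15 unfolded protein response genes passed, although the list had a camera call (camera adjusted p = 2.87e-04, adjusted p = 0.264 with an estimated correlation). The same held for the 30 G2/M genes (camera adjusted p = 9.54e-04, adjusted p = 0.386 with an estimated correlation). *PTHLH* (-1.04 ± 0.25) fell, and *CTRB1* (-1.22 ± 0.30) fell but shares reads with its paralog *CTRB2*. With edgeR, 413 genes passed, 218 higher and 195 lower, 23 higher and 7 lower at least 2-fold, and 770 genes when only these 6 libraries were fitted. The share of higher calls ran from 49.7% with DESeq2 to 60.1% with upper quartile scaling. With 1 library fewer the count ran from 222, when replicate B without dox was left out, to 295. Of 54 genes chosen for naming in this comparison, 27 did not pass with some library left out, *PTHLH* and *CTRB1* among them, and none reversed.

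The difference between the dox responses of the lines sets the response of the inducible line against that of dox alone. In it *FLNC* (8.47 ± 0.53) and *MCAM* (7.27 ± 0.27) stood higher, and *TNFSF18* (-7.33 ± 0.16), *SPARC* (-6.21 ± 0.23), *SPP1* (-6.15 ± 0.26) and *CLCA2* (-6.27 ± 0.34) lower. All 38 interferon-stimulated genes were lower (camera adjusted p = 3.04e-33), with *IFIT3* at -2.88 ± 0.14. 21 of 24 cholesterol genes were higher and 1 lower (camera adjusted p = 2.58e-16), with *DHCR7* at 1.82 ± 0.09. 5 of 19 basal markers were higher and 14 lower (camera adjusted p = 4.27e-06), with *TP63* at -4.15 ± 0.10. 4 of 31 squamous genes were higher and 15 lower (camera adjusted p = 1.83e-05, adjusted p = 0.199 with an estimated correlation), with *DSG1* at -5.61 ± 0.10. 7 of 21 mesenchymal genes were higher and 9 lower (camera adjusted p = 4.27e-06), and 1 of 8 fibroblast markers was higher and 3 lower (camera adjusted p = 7.37e-05). 13 of 13 mitochondrially encoded mRNAs were lower (camera adjusted p = 1.20e-05, adjusted p = 0.319 with an estimated correlation). 4 of 20 EZH2-repressed genes were higher and 9 lower (camera adjusted p = 0.0265, adjusted p = 0.319 with an estimated correlation). 10 of 27 SWI/SNF subunits were higher and 5 lower (camera adjusted p = 0.0342, adjusted p = 0.173 with an estimated correlation). This list contains the induced *ARID1A* itself (4.51 ± 0.07), and camera was not run without it. 13 of 30 G2/M genes were higher and 3 lower (camera adjusted p = 0.0385, adjusted p = 0.618 with an estimated correlation), and 20 were higher and 3 lower without the replicate A that stood apart. With edgeR, 10089 genes passed, 4945 higher and 5144 lower, with 1196 higher and 2283 lower at least 2-fold. Higher calls were 49.0% of these and 46.4% to 52.5% under the other scalings. The total equals that of CPI-0209 in the control line without dox, with another division into higher and lower.

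The difference of the CPI-0209 response with and without dox in the ARID1A line asked whether induced *ARID1A* changes the response to EZH2 inhibition. All 15 unfolded protein response genes had lower log2 responses with dox (camera adjusted p = 5.73e-59), with *HSPA5* at -1.67 ± 0.07 (edgeR adjusted p = 3.67e-19) and *SDF2L1* at -2.48 ± 0.10. This rests on their rise in the 3 libraries with CPI-0209 and no dox. A culture condition of that group cannot be told apart from an effect of induced *ARID1A*. 1 of 25 integrated stress response genes was higher and 22 lower (camera adjusted p = 1.30e-29), with *STC2* at -2.03 ± 0.09. 18 of 31 squamous genes were lower (0 higher and 19 lower adjusted over the list alone; camera adjusted p = 7.11e-22), with *SBSN* at -3.80 ± 0.18 and *S100A9* at -2.33 ± 0.10. Part of the *SBSN* difference was a higher start. With DMSO its libraries ran from 7.17 to 7.98 CPM with dox and from 0.769 to 1.33 CPM without. With CPI-0209 they ran from 63.9 to 74.6 CPM with dox and from 124 to 157 CPM without. 8 of 11 class II genes were lower (0 higher and 9 lower adjusted over the list alone; camera adjusted p = 1.29e-05, adjusted p = 0.0861 with an estimated correlation), with *CIITA* at -1.76 ± 0.17. With CPI-0209, *HLA-DRA* stood at 16.6 ± 1.59 CPM with dox and 17.6 ± 0.228 CPM without.

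In several other groups most differences that passed were also negative, which includes genes that CPI-0209 lowered with dox. CPI-0209 with dox raised 2 of 22 epithelial genes and lowered 16, and raised 5 of 22 luminal markers and lowered 12. In the difference, 3 of 22 epithelial genes were higher and 14 lower (5 higher and 14 lower adjusted over the list alone; camera adjusted p = 7.18e-06). 1 of 22 luminal markers was higher and 17 lower (camera adjusted p = 3.52e-06, adjusted p = 0.0861 with an estimated correlation). 2 of 19 basal markers were higher and 11 lower (camera adjusted p = 1.34e-05, adjusted p = 0.0520 with an estimated correlation). 3 of 28 chemokines and NF-kB targets were higher and 10 lower (camera adjusted p = 7.18e-06, adjusted p = 0.0997 with an estimated correlation), with *TNFAIP3* at -1.15 ± 0.07. In the other direction, 26 of 38 interferon-stimulated genes were higher and 1 lower (27 higher and 1 lower adjusted over the list alone; camera adjusted p = 7.34e-09, adjusted p = 0.253 with an estimated correlation), with *HERC5* at 0.78 ± 0.10. 9 of 13 mitochondrially encoded mRNAs were higher (11 higher and 0 lower adjusted over the list alone; camera adjusted p = 5.98e-04, adjusted p = 0.329 with an estimated correlation), and 5 to 10 were with 1 library left out. Without the replicate A that stood apart, no epithelial gene was higher and 15 were lower, and no basal marker was higher and 12 were lower. *ADAMTS8* went from no count to 9.56 ± 0.708 CPM without dox and from 0.0825 to 0.419 ± 0.0455 CPM with dox. The engulfment gene *ELMO1* reached 2.41 ± 0.338 CPM with dox and 0.207 ± 0.0841 CPM without. With edgeR, 6533 genes passed, 3297 higher and 3236 lower. Higher calls were 50.5% of these, 37.7% with RLE size factors and 36.7% with DESeq2.

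In the control line the CPI-0209 response differed with dox in few genes. *TMC3* (2.53 ± 0.40), *SLFN5* (1.17 ± 0.19), *NIPAL4* (1.61 ± 0.32) and *SLC5A2* (1.96 ± 0.38) had higher log2 responses with dox, as did the matrix genes *FN1* (0.44 ± 0.07) and *TGFBI* (0.59 ± 0.09), of which *TGFBI* fell without dox (-0.59 ± 0.06). With edgeR, 24 genes passed, all higher with dox and none lower, against 910 genes at an unadjusted p under 0.05 and 32 by DESeq2. With 1 library fewer the count ran from 8, when replicate B with CPI-0209 and no dox was left out, to 26. Of 9 genes chosen for naming in this comparison, 4 did not pass with some library left out, *NIPAL4* and *SLC5A2* among them, and none reversed. No interferon-stimulated gene passed over all genes, and 3 higher and 0 lower did when adjusted over the list alone (camera adjusted p = 3.66e-16, adjusted p = 0.199 with an estimated correlation).

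The difference of the CPI-0209 response between the lines without dox compared the clone with the control line before induction. All 15 unfolded protein response genes had higher log2 responses in the ARID1A line (camera adjusted p = 3.75e-131), *HSPA5* by 1.68 ± 0.07 (edgeR adjusted p = 6.70e-19). This rests on the same 3 libraries of the ARID1A line with CPI-0209 and no dox, so it is not a separate observation. 20 of 25 integrated stress response genes were higher (21 higher and 0 lower adjusted over the list alone; camera adjusted p = 4.27e-50), with *STC2* (1.96 ± 0.10) and *PSAT1* (1.45 ± 0.08). 10 of 11 class II genes were higher (camera adjusted p = 1.46e-11), with *CIITA* (1.01 ± 0.19) and *CD74* (2.08 ± 0.22). 21 of 38 interferon-stimulated genes were lower (0 higher and 30 lower adjusted over the list alone; camera adjusted p = 9.06e-13, adjusted p = 0.218 with an estimated correlation), with *HERC5* at -0.84 ± 0.10, and 12 to 28 were with 1 library left out. 8 of 30 S phase genes were lower (1 higher and 15 lower adjusted over the list alone; camera adjusted p = 5.99e-05, adjusted p = 0.104 with an estimated correlation), and 4 to 8 were with 1 library left out. 3 of 19 basal markers were higher and 7 lower (camera adjusted p = 2.64e-04, adjusted p = 0.104 with an estimated correlation). 1 of 22 epithelial genes was higher and 8 lower (1 higher and 10 lower adjusted over the list alone; camera adjusted p = 6.26e-05, adjusted p = 0.0657 with an estimated correlation). The ephrin receptor *EPHA3* had a higher log2 response in the ARID1A line (6.59 ± 0.28), where it went from 0.134 ± 0.0870 to 6.09 ± 0.200 CPM, against 6.05 ± 0.0950 to 2.71 ± 0.321 CPM in the control line. *NXN* (ENSG00000167693, chromosome 17, 799313 to 979770) had a lower one (-3.86 ± 0.11). It went from 65.3 ± 1.70 to 133 ± 2.37 CPM in the ARID1A line and from 3.68 ± 0.608 to 109 ± 5.28 CPM in the control line. With edgeR, 2386 genes passed, 1204 higher and 1182 lower, with 421 higher and 158 lower at least 2-fold. Higher calls were 50.5% of these and 54.9% to 58.0% under the other scalings.

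The lines also differed without dox or drug. Germline and cancer-testis genes were lower in the ARID1A line, with *SSX1* at 29.8 ± 0.561 CPM in the control line and 3.60 ± 0.364 CPM in the ARID1A line and *MAGEC2* at -2.71 ± 0.12. 1 of 21 of them was higher and 18 lower (camera adjusted p = 1.02e-15), the *MAGE* genes being uncertain between paralogs. 13 of 19 basal markers were higher and 3 lower (camera adjusted p = 2.81e-10), with *CD44* (1.70 ± 0.05) and *KRT17* (2.11 ± 0.08). 32 of 38 interferon-stimulated genes were higher and 2 lower (33 higher and 3 lower adjusted over the list alone; camera adjusted p = 6.46e-10, adjusted p = 0.367 with an estimated correlation), with *HERC5* (1.22 ± 0.07) and *IFIT3* (1.04 ± 0.09). 17 of 28 chemokines and NF-kB targets were higher and 6 lower (17 higher and 7 lower adjusted over the list alone; camera adjusted p = 7.78e-06, adjusted p = 0.171 with an estimated correlation). 16 of 25 immediate-early genes were higher and 1 lower (17 higher and 2 lower adjusted over the list alone; camera adjusted p = 2.44e-05, adjusted p = 0.447 with an estimated correlation). 16 of 30 G2/M genes were lower (0 higher and 17 lower adjusted over the list alone; camera adjusted p = 0.00376, adjusted p = 0.447 with an estimated correlation). 1 of 8 fibroblast markers was higher and 4 lower (2 higher and 4 lower adjusted over the list alone; camera adjusted p = 0.00181), with *COL1A2* at -2.56 ± 0.09. 11 of 22 epithelial genes were higher and 4 lower (camera adjusted p = 0.00103, adjusted p = 0.159 with an estimated correlation). 8 of 11 class II genes were lower (0 higher and 9 lower adjusted over the list alone; camera adjusted p = 0.0295, adjusted p = 0.447 with an estimated correlation). *PECAM1* (5.61 ± 0.29), *COL21A1* (4.90 ± 0.11) and *NXN* (4.15 ± 0.09) were among the genes highest above the control line, and *HSD3B1* (-6.66 ± 0.26) and *ARMCX3* (-6.62 ± 0.24) among those furthest under it. With edgeR, 7729 genes passed, 3798 higher and 3931 lower, with 750 higher and 1048 lower at least 2-fold. Clone and construct cannot be separated with 1 clone.

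The CPI-0209 response of the control line and the dox response of the ARID1A line, which share no library, were set side by side. The question was whether EZH2 inhibition and *ARID1A* induction move the same genes. Among genes at least 2-fold higher in both were the carbonic anhydrase *CA12* (5.27 ± 0.23 with CPI-0209 and 4.64 ± 0.27 with dox), the scaffold *AKAP12* (5.44 ± 0.15 and 5.72 ± 0.15), *FLNC* (4.59 ± 0.19 and 8.58 ± 0.12) and the sodium channel subunit *SCNN1G* (4.77 ± 0.24 and 5.14 ± 0.26). Among genes lower in both were *MYCL* (-1.56 ± 0.07 and -3.30 ± 0.09), *RARRES1* (-1.93 ± 0.10 and -2.12 ± 0.10), *FOSB* (-1.88 ± 0.18 and -3.60 ± 0.20) and *COL3A1* (-1.70 ± 0.06 and -4.30 ± 0.07). At least 2-fold higher in both were 776 genes where 249 were expected from independent sets (odds ratio 6.33, one-sided Fisher's exact p = 1.03e-232). At least 2-fold lower in both were 128 where 31.6 were expected (odds ratio 7.10, one-sided Fisher's exact p = 1.14e-48). Under 1 CPM in the untreated group stood 74.7% of the genes at least 2-fold higher with CPI-0209 and 63.6% of those with dox. Of all tested genes 29.4% and 29.7% did. The expected numbers did not allow for this, so an excess of higher genes at equal starting level was not tested. Without a minimum fold, 1965 were higher in both where 1643 were expected, and 2232 lower in both where 1416 were expected. Effects also went against each other, since 457 genes rose at least 2-fold with CPI-0209 and fell at least 2-fold with dox (360.0 expected) and 9 did the reverse (21.9 expected). Across all tested genes the log2 fold changes correlated weakly (Pearson 0.257, Spearman 0.212), and genes are not independent replicates. The Pearson value was 0.123 with no filter and 0.146 with DESeq2. Both runs included genes that the filter removed, so its size depended on the processing.

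**Figure D4:**
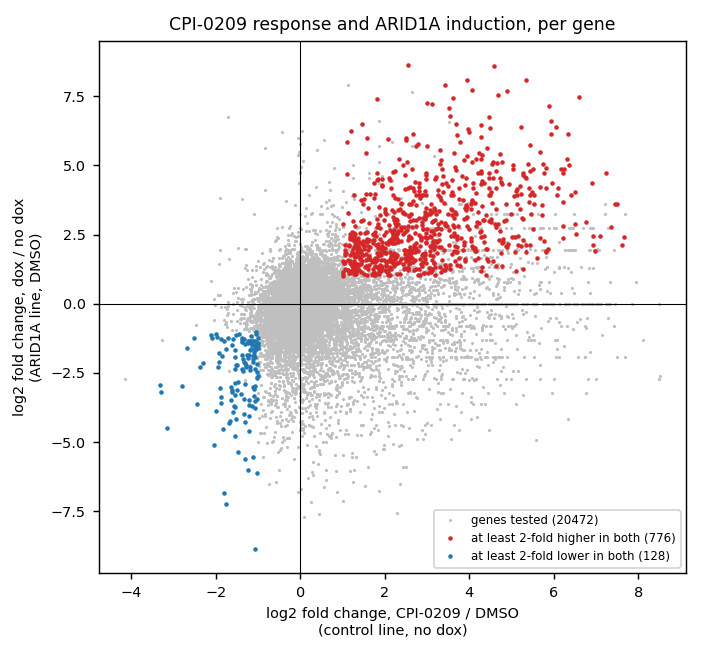
Log2 fold change of CPI-0209 against DMSO in the control line without dox (horizontal) and of dox against no dox in the ARID1A line with DMSO (vertical), 1 dot per tested gene. The 776 genes at least 2-fold higher in both and the 128 at least 2-fold lower in both are coloured, out of 20472.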

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

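The tests of the 3 weighed patterns, the splits for CPI-0209 in the control line without dox and those for the dox difference of its response in the ARID1A line were chosen only after the result was seen.

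Effects that differed between groups came from tests of the difference itself. The dox response differed between the lines in 10089 genes by edgeR. Among the genes named for the largest differences, the tumour necrosis factor family ligand *TNFSF18* passed in opposite directions (log2 difference -7.33). It fell by 6.69 on the log2 scale in the ARID1A line and rose in the control line (0.64 ± 0.08). In the control line 24 genes had another CPI-0209 response with dox, among them the immune checkpoint ligand *VTCN1* (log2 difference 1.00), which changed by 0.65 ± 0.12 with dox and -0.35 ± 0.12 without. In the ARID1A line 6533 genes had another CPI-0209 response with dox. Between the lines the CPI-0209 response differed in 2386 genes, with *EPHA3* (log2 difference 6.59) higher by 5.43 ± 0.24 in the ARID1A line and lower in the control line (-1.16 ± 0.13). Of the genes whose difference passed and that passed in both arms, the arms went in opposite directions in 116 of 316 for dox between the lines, 840 of 2375 for CPI-0209 by dox in the ARID1A line, 4 of 16 for that in the control line and 215 of 1314 for CPI-0209 between the lines.

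Other splits of the libraries were fitted with only the groups compared. For these interactions 1 of the 40 splits gave as many genes, the real one. Splits that mix the labels of an arm put its treatment effect into the residual spread, and only 4, 8, 6 and 8 other splits gave any gene. The low share is therefore largely fixed by the design and does not settle chance. The real values were 9224 for the dox difference between lines (highest other 9197, a split that keeps the ARID1A line's labels), and 5414 for the CPI-0209 difference with dox in the ARID1A line (highest other 3688, which keeps the DMSO labels). They were 33 for that difference in the control line (highest other 28, which keeps the CPI-0209 labels), and 3204 for the CPI-0209 difference between lines (highest other 2791, which keeps the DMSO labels). For pairwise comparisons 10 splits are too few for a share under 0.05. There the highest other split gave 0 genes, against real values of 9805, 10509, 10518 and 6999 for CPI-0209 (control line without and with dox, then ARID1A line without and with dox), 10238 and 770 for dox in the ARID1A and control lines and 8837 between the lines. For the genes shared by CPI-0209 in the control line and dox in the ARID1A line, 1 of the 200 pairs of splits gave as many, but the other splits of each comparison gave no gene, so this share is fixed by the design and does not settle chance. The real values were 1832 higher and 1870 lower, and the highest other pairs gave 1147 and 1107, from the real splits with 1 direction reversed.

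The weighed pattern of endoplasmic reticulum stress was that CPI-0209 raised all 15 unfolded protein response genes in the uninduced ARID1A line. A single library is argued against, because 15 of the 15 genes stayed higher with each of the 6 libraries left out. Scaling is argued against, because the lowest median log2 fold change of the 15 under the other scalings was 1.28. A culture condition of the treated libraries other than the drug, such as depleted medium, cannot be told apart from a drug effect. It remains possible, since the CPI-0209 libraries were 1 group. Only 3 of the 15 genes were higher in this line than in the control line without drug, fewer than a condition of the whole line would give. A drug effect in this clone stays open as a hypothesis.

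A further weighed pattern was that dox raised 23 genes at least 2-fold in the control line, led by *GALNT16*. Induced cells or reads in the control libraries are argued against by *ARID1A*. At the share of 13.9% that *GALNT16* needs, it would stand at 611 CPM, not 120.3. 7 other genes of the induced line allow a median share of 0.0466% (0.398% at most). Genes at least 2-fold higher with dox in the control line were left out of these 7, which favoured a low share in advance. Of the 23 genes, 13 were also higher with dox under CPI-0209 in separate libraries, which is consistent with an effect of dox itself. Both lines carried the dox-responsive system, so an effect of dox through that system stays open.

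The last weighed pattern was the baseline difference of the lines. If *ARID1A* made without dox were its main cause, the line difference would follow the dox response. The line difference under CPI-0209 correlated with the dox response under DMSO at -0.125 across genes (Spearman -0.153, genes are not independent replicates). The uninduced ARID1A line is added in the former and subtracted in the latter, which can make this value negative in either case. The test therefore cannot decide, and *ARID1A* itself stood higher in the uninduced ARID1A line (172 against 132 CPM). Of 728 genes changed at least 2-fold in both, 264 went the same way (178 expected) and 464 the opposite way (173 expected). Clone and construct cannot be separated in this design and stay open, and *ARID1A* made without dox stays open with them.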

How the results depend on the processing

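Of the alternatives, the lists without 1 library were tests chosen only after the data were seen. Under RLE and upper quartile scaling, the stricter filter, DESeq2 and the block, all 11 counts of genes stayed within 1.5 times those reported (ratios 0.886 to 1.33). With only the groups compared the dox count of the control line was 770 (419 higher and 351 lower). With no filter the control line's difference in CPI-0209 response by dox was 37 (36 higher and 1 lower). Fitting only the groups compared also lowered the count for CPI-0209 in the ARID1A line with dox, to 6999 (ratio 0.706). The count for dox in that line with DMSO fell to 10238. The cause of these shifts was not tested. A minimum log2 fold change of 1 lowered the counts by construction, for CPI-0209 to 3356 and 3422 in the control line without and with dox and 3371 and 2870 in the ARID1A line, for dox to 4041 in the ARID1A line and 30 in the control line, for the line comparison to 1798, and for the differences to 3479 (dox between lines), 1306 and 4 (CPI-0209 by dox in the ARID1A and control lines) and 579 (CPI-0209 between lines). It left 776 shared higher and 128 shared lower genes. Under the other alternatives the shared genes numbered 1832 to 2167 higher and 1781 to 2310 lower, all over expectation. The correlation of the CPI-0209 and dox responses was 0.123 with no filter and 0.146 with DESeq2, both of which included genes that the filter removed. It was 0.277 with the stricter filter and 0.277 with only the groups compared. Whether the added genes caused the lower values was not tested. Calls of gene lists went from 117 to 44 with an estimated correlation and to 190 with fry. The *EZH2* difference in CPI-0209 response by dox in the ARID1A line passed nowhere and reversed in sign, to -0.0319 with RLE, -0.0310 with no filter, -0.0143 with the stricter filter and -0.0333 with DESeq2; the cause was not tested.

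With each library left out in turn, the counts ran from 8932 to 9451 and 9297 to 9875 for CPI-0209 in the control line without and with dox, and from 9473 to 9709 and 9130 to 10654 in the ARID1A line. They ran from 11774 to 12339 for dox in the ARID1A line, 6716 to 6930 between lines, 9535 to 10406 for the dox difference, 5459 to 7502 for the CPI-0209 difference by dox in the ARID1A line and 1875 to 2279 for that between lines. Shared genes ran from 1899 to 2170 higher and 1836 to 2188 lower, and their correlation from 0.224 without ARID1A line with dox and DMSO replicate A to 0.273 without the uninduced replicate A (0.227 and 0.234 without induced replicates B and C). Dox in the control line gave 222 to 295 genes, with 267, 222 and 258 without DMSO replicates A, B and C, and 234 and 236 without dox replicates B and C. The CPI-0209 difference by dox in the control line gave 8 to 26 genes. It gave 11, 15 and 14 without the DMSO replicates A, B and C, 15, 11 and 12 without those with dox, 13 and 8 without CPI-0209 replicates A and B, and 9 and 13 without dox and CPI-0209 replicates A and B. Leaving out a library also removes its share of the residual degrees of freedom.

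Of the 1263 named pairs of gene and comparison, RLE kept 1248, upper quartile 1245, no filter 1227, the stricter filter 1247, DESeq2 1239 and only the groups 1221, and none reversed. With single libraries left out, 27 of 54 named genes did not always pass for dox in the control line and 4 of 9 for its difference in CPI-0209 response by dox, against 8 to 14 of 98 to 151 in the other comparisons, and none reversed. Most of one direction changed sides under another scaling for SWI/SNF subunits with CPI-0209 in the control line without and with dox, and for p53 targets in the dox difference. No scaling moved the median of all genes by more than 0.0732.

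The replicate letters did not pair the samples. Same-letter deviations of different groups correlated at 0.000846 on average (-0.0938 to 0.10 over 84 pairs, against -0.000425 for other letters), and 10 of the 24 libraries correlated best with their own letter. The replicate block gave counts 0.995 to 1.08 times those reported, kept all 1263 named pairs and gave 1948 shared higher and 2235 shared lower genes. Depth limits genes near the floor, and each named bound covers counting error only.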

Other observations

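The gene families and the comparison of genes matched on the dox response were tests chosen only after the result was seen. Families were formed from the shared root of official symbols, 196 with at least 10 of the 15141 tested protein-coding genes. In the control line without dox, CPI-0209 raised keratins most clearly, 23 of 40 at least 2-fold where 6.58 were expected (one-sided Fisher's exact adjusted p = 8.38e-07), with *KRT81* from 1.62 to 17.1 CPM and *KRT5* from 36.7 to 263 CPM. Interleukins and their receptors followed, 27 of 59 where 9.71 were expected (adjusted p = 1.24e-05). Mucins rose for 10 of 13, among them *MUC4* from 0.808 to 10.0 CPM, collagens for 18 of 38, kallikreins for 8 of 11, among them *KLK1* from 0.603 to 15.3 CPM, and CC chemokines for 8 of 10, among them *CCL5* from 1.60 to 11.4 CPM.

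Dox in the ARID1A line lowered 19 of 40 keratins (one-sided Fisher's exact adjusted p = 8.54e-07) and 15 of 38 collagens at least 2-fold, and 7 of 10 tested *SOX* genes, among them *SOX7* from 16.8 to 3.42 CPM. It raised 18 of 59 interleukins and their receptors at least 2-fold where 4.86 were expected (one-sided Fisher's exact adjusted p = 1.29e-04), and lowered 8. It also raised 6 of 14 *GALNT* glycosyltransferases, which missed the threshold (adjusted p = 0.0507). Keratins also included 6 that rose at least 2-fold with dox, such as *KRT34* from 0.270 to 19.1 CPM. In the uninduced ARID1A line 9 of 11 protocadherin gamma A genes were lower (adjusted p = 4.66e-08), among them *PCDHGA4* from 4.43 to 1.10 CPM. These genes share exons, so they are not separate observations.

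A hypothesis written before its result was that CPI-0209 and *ARID1A* act through a saturable route, so that genes raised by both would respond less to dox once CPI-0209 is present. Of 776 such genes 492 (63.4%) were still at least 2-fold higher with dox under CPI-0209. Of the genes raised by dox alone 531 of 876 (60.6%) were (two-sided Fisher's exact p = 0.264). By the rule written beforehand, a share not lower than that of the genes raised by dox alone went against the hypothesis, as here. The sets began from unequal dox responses with DMSO (medians 2.40 and 1.36), a limit that the rule did not hold and that weakens this comparison. With 419 genes of each set matched on the response with DMSO, the median log2 dox response under CPI-0209 was 1.04 for genes raised by both and 1.55 for genes raised by dox alone. The difference was -0.51, with a permutation p of 1e-05 across genes, the smallest that 100000 permutations can give. Genes are not independent replicates, so this p does not measure the spread between samples. The sets were not matched on starting level. A shared saturable route would give a difference of this sign. Effects that add on the linear scale could give it too, which was not modelled, so the route stays undecided.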
